A study of Mus musculus with 6 samples.

How the data were processed

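RNA was measured in 6 mouse embryo heads at E10.5, 3 labelled wild type (WT) and 3 labelled Tasp1 knockout (KO). Per the labels' protocols, heterozygous parents were intercrossed, the forebrain and midbrain part of each head was dissected, and biotin-labelled RNA was made from 100 ng of total RNA per sample. Each sample was read on 1 Affymetrix array.

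The deposited table holds log2 signals, 1 value per probe set and array, for 35556 probe sets. The values ran from 2.73 to 14.4, with array medians between 7.35 and 7.45, and their quantiles nearly coincided across arrays. They were therefore taken as already normalised between arrays. The submitters' processing notes name Affymetrix Expression Console and MAS5, without versions or roles. The values are not MAS5 signals on the linear scale, and how background was subtracted, arrays were scaled and probes were summarised is not given in the sources used here. The design written before the data were examined had expected linear signals with a pseudocount, with the log2 values to be used as they are if they were on that scale already. They were used so, with no pseudocount and no further scaling. The number of arrays limits the precision: with 3 against 3, an exact two-sided permutation test cannot give a p below 0.1.

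Genes were named from the platform annotation. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed there and are unnamed here. For 21698 of those with 1 symbol, the gene identifier matched the gene table of assembly GRCm38.p6, and 0 symbols needed an update. The genome build behind the array's annotation is not given in the sources used here, so that table served only for names, chromosomes and the order of neighbouring genes, and no coordinates are printed. Probe sets with 1 symbol were kept, the 40% with the lowest mean over all 6 arrays (below a log2 signal of 7.06) were left out, and each gene was represented by its probe set with the highest mean, whatever its other probe sets showed. This left 11802 genes.

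KO-labelled and WT-labelled heads were compared with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences are KO-labelled minus WT-labelled, in log2 units, with the standard error (SE) of that fit. Gene lists fixed before the data were examined cover Taspase1 and its substrates, transcription, cell cycle, p53 targets, patterning, signalling pathways, and markers of cell types that the dissected tissue could hold. Of 24 lists, the sex-linked markers were read per array only, and 23 were tested with camera at a preset correlation of 0.01, with adjustment over the 23 lists. Camera with an estimated correlation and fry were alternatives. Counts "adjusted over the list alone" use Benjamini-Hochberg within 1 list.

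Genes were named by a rule also fixed beforehand. Since fewer than 10 genes passed the threshold, it took the 10 higher and the 10 lower genes with the smallest unadjusted p. To these it added Tasp1, Gtf2a1, Kmt2a, Kmt2b and Cdkn2a, and, for each list, up to 4 members with the smallest unadjusted p. A condition that these members have an unadjusted p under 0.05 was not part of that rule and was added afterwards. Genes named outside the rule to spell out a count or a head that stands apart (Usf2, further p53 targets, and genes called only with a head left out or without the filter) were chosen after their values were seen. Cdkn2a fell below the brightness filter, so its values come from the same fit without the filter.

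The labels number the replicates 1 to 3 in both groups but state no pairing, and heads with the same number did not deviate together, so the replicate number was not used as a block. The alternatives were quantile normalization, median centring, 1 or 64 added on the linear scale, no filter or a 60% filter, the mean of a gene's probe sets, all probe sets, other variance models, other thresholds, the replicate block, Xist signal as a covariate, genes of the sex chromosomes left out, and each head left out in turn. Array quality weights and the omission of genes on the chromosome of Tasp1 were added after seeing the data.

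The procedure was tested on simulated data drawn from the real means and the fitted spreads of the 11802 genes, for 3 against 3 heads, with independent genes. Of 200 genes changed by known folds, it recovered 51 of 67 (76.1%) at 1.25-fold, 67 of 67 at 1.5-fold and 66 of 66 at 2-fold, and 5 unchanged genes were called. With no gene changed, 1 gene and 0 lists were called. With the p53 target list alone raised 1.1-fold, 1 list was called. With 200 planted changes, independent genes and spreads as moderated by limma, the recovered shares are not detection rates of the real comparison. In the real comparison, Lgi1 at 1.51 times had a limma adjusted p of 0.228 and Gmnc at 0.63 times one of 0.079. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.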

Results

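Transcript levels were measured on arrays in the dissected heads of 6 mouse embryos at E10.5, when the forebrain and midbrain vesicles are growing. There were 3 heads labelled WT and 3 labelled Tasp1 KO, each a separate embryo per the labels. Tasp1 encodes Taspase1, a protease that cleaves the histone methyltransferases encoded by Kmt2a and Kmt2b and the precursor of transcription factor TFIIA encoded by Gtf2a1. The comparison asked which transcripts depend on Taspase1 in the developing head. Values are deposited log2 signals, and differences are KO-labelled minus WT-labelled.

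The arrays were alike over the genes tested, with Pearson correlations between pairs of arrays, across genes, from 0.989 to 0.996. WT 1 lay farthest from the others on the first principal component, at −13.3, where the other 5 heads lay between −1.06 and 6.20. WT 2 was the only head with a high Xist signal, 12.3 against 4.90 to 5.24 in the other heads. Its signals of the Y-linked genes Kdm5d, Uty and Eif2s3y were 5.48, 4.72 and 4.52, where the other heads had 9.42 or more. WT 2 thus had the pattern of a female, and the other 5 heads, all KO-labelled heads among them, that of males. Sex was therefore not balanced between the groups, and it was not among the labels used here. Leaving out WT 1 or WT 2, or adding Xist signal as a covariate, was among the alternatives fixed before the data were examined. These were applied to the counts of genes and of lists, the genes named by the rule and the 4 called lists.

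In the KO-labelled heads, target genes of p53 rose as a list, led by Ccng1 and Phlda3 at 1.42 and 1.27 times the WT-labelled level, with a preset correlation, but not with an estimated one (adjusted p = 0.061). Gtf2a1, a gene whose product Taspase1 cleaves, was 1.29 times as high. Genes of neuronal differentiation and of the eye and lens fell as lists with the preset correlation, and these calls were lost too with an estimated correlation (adjusted p = 0.77 and 0.54). With the preset correlation 4 lists were called in all, and 8 of the 10 splits of the 6 heads into 3 and 3, the real one included, gave 4 or more. The other splits mix the labels unevenly and so still hold part of any difference between them. Over all genes tested, 0 genes passed the threshold in limma, against 841 at an unadjusted p under 0.05.

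The Tasp1 signal (probe set 10488090) was not lower in the KO-labelled heads. It read 8.63, 8.63 and 8.50 in the KO-labelled heads and 8.10, 8.45 and 8.49 in the WT-labelled heads. The means were 8.59 ± 0.08 and 8.34 ± 0.21 (SD, n = 3 each), a difference of +0.24 that did not pass the test (limma, adjusted p = 0.67; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). Without WT 1 the difference was +0.12. Where the probe set lies relative to the deleted part of the gene is not given in the sources used here, so its signal does not check the labels, and heads are called KO-labelled and WT-labelled throughout.

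Among the cleaved proteins' genes, Gtf2a1 had the clearest difference. Its signal (probe set 10401882) was 10.85 ± 0.10 in KO-labelled and 10.48 ± 0.03 in WT-labelled heads (SD, n = 3 each), 1.29 times as high, with every KO-labelled head above every WT-labelled head. It did not pass adjustment over all genes (limma, difference +0.37, SE 0.05, adjusted p = 0.107), but passed when adjusted over the list alone (adjusted p = 2.7e-04). Kmt2a differed by +0.12 (95% confidence interval −0.10 to 0.33) and Kmt2b by +0.02 (−0.11 to 0.15), and neither passed (limma, adjusted p = 0.84 and 0.97). Usf2 differed by −0.07, and the remaining member, Gtf2a1l, fell below the brightness filter and was not tested. The list of Taspase1 and its substrates, with 5 genes tested, was shifted upward as a list (median +0.12, 4 higher and 1 lower, camera adjusted p = 0.028). That call was lost with an estimated correlation (adjusted p = 0.54), without KO 3 (adjusted p = 0.050), and without WT 1, where the median was −0.014 (adjusted p = 0.18). Tasp1 itself is a member.

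**Figure D1:**
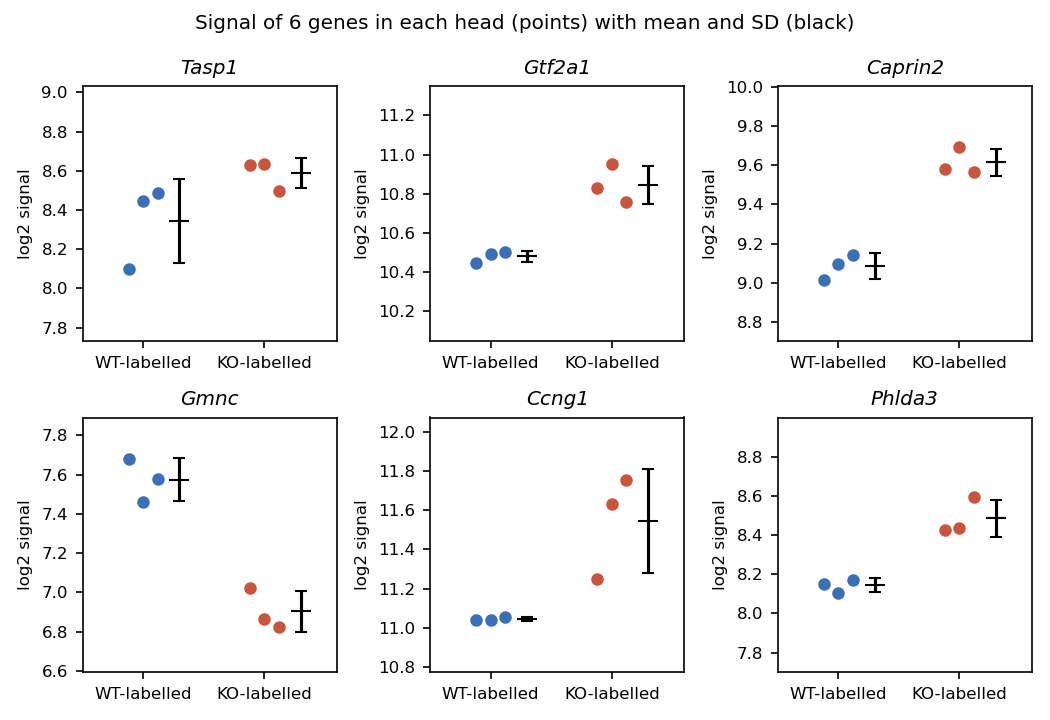
Log2 signal (y axis) of 6 genes in each of the 3 WT-labelled and 3 KO-labelled heads (x axis); points are single heads, black bars the group mean and SD, and each panel spans the same range of log2 signal. The Tasp1 values of the groups lie between 8.10 and 8.63, Gtf2a1, Caprin2, Ccng1 and Phlda3 are higher and Gmnc lower in every KO-labelled head, and Ccng1 in KO 1 reads 11.3 against 11.6 and 11.8 in KO 2 and KO 3.

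Cdkn2a, which encodes the cell cycle inhibitors INK4A and ARF, was dim in both groups, brighter than only 30.3% of the probe sets with 1 gene symbol. It read 6.45 ± 0.03 in KO-labelled and 6.39 ± 0.06 in WT-labelled heads (SD, n = 3 each; exact permutation test, two-sided p = 0.3). The 95% confidence interval of the ratio ran from 0.93 to 1.17, in the limma fit without the brightness filter. The list of CDK inhibitors (7 genes, 5 tested, Cdkn2a and Cdkn1a not among them) had a median of −0.07 and was not called (camera adjusted p = 0.62). Genes of the cell cycle and of E2F targets (48 tested) had a median of −0.02, 17 higher and 31 lower (adjusted p = 0.97). Rbl1 (+0.19), Cdk6 (+0.24), Pcna (+0.10) and Ccnd2 (+0.08) had its smallest p-values (Rbl1 and Pcna lie on chromosome 2), and 0 members passed when adjusted over the list alone.

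Over all 11802 genes, 0 passed the threshold in limma and 0 in an ordinary linear model per gene, against 841 in limma at an unadjusted p under 0.05, where 590.1 are expected by chance. Of these 841, 292 were higher and 549 lower in KO-labelled heads. The ranges of the groups did not overlap for 12.3% of genes, where chance gives 10%. The genes with the smallest p-values on the higher side were led by Caprin2, an RNA-binding protein gene (9.61 ± 0.07 against 9.08 ± 0.07, SD, n = 3 each; 1.44 times as high, adjusted p = 0.064). Dgat2, which encodes an enzyme of the last step of triglyceride synthesis (+0.48, adjusted p = 0.084), and Entpd4, a nucleotide phosphatase gene (+0.32, adjusted p = 0.101), followed. The other higher genes that the rule names were Gtf2a1, Tmem30b (+0.52), the kinetochore gene Knl1 (+0.25), Polr2a (+0.23), which encodes the largest subunit of RNA polymerase II, the hypothalamic transcription factor gene Sim1 (+0.31), Styx (+0.27) and Lgi1 (+0.60). Their adjusted p-values in limma ran from 0.107 to 0.228.

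On the lower side stood Gmnc, a regulator of multiciliated cells (6.90 ± 0.11 against 7.57 ± 0.11, SD, n = 3 each; 0.63 times, adjusted p = 0.079). Its KO-labelled mean lies below the brightness cut of 7.06, so 0.63 is a ratio of signals and not of transcripts. The Gmnc difference of −0.67 ran from −0.73 to −0.47 over the alternatives that keep all heads. The mitochondrial ribosomal protein gene Mrpl48 (−0.42), the tocopherol transfer protein relative Ttpal (−0.53), the histone chaperone gene Anp32e (−0.34), Serinc3 (−0.25), the small nucleolar RNA Snord104 (−0.34), Wfdc2 (−0.59), Tmem50b (−0.26), the melanosome gene Pmel (−0.50) and E330013P04Rik (−0.31) followed, with adjusted p-values in limma from 0.107 to 0.228. All 20 genes had every KO-labelled head on one side of every WT-labelled head. Knl1, Ttpal, Serinc3 and Wfdc2 lie on chromosome 2, as Tasp1 does, in assembly GRCm38.p6. On that chromosome 41 of 939 tested genes (4.37%) had an unadjusted p under 0.01, against 163 of 10840 elsewhere (Fisher's exact test, two-sided p = 2.5e-08). Without KO 1, limma called 6 genes (Cxcl13, Ccng1, Robo3, Snap23, which also lies on chromosome 2, Gmnc and Caprin2), and without WT 1 it called Sst alone.

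Target genes of p53, the transcription factor that responds to DNA damage and other stress, rose as a list in the KO-labelled heads with the preset correlation. The list holds 30 genes, of which 22 were tested. Cdkn1a, Bax, Bbc3, Pmaip1, Eda2r, Fas, Gdf15 and Ephx1 had no probe set with 1 symbol above the brightness filter and were not tested. Of the 22 tested, 17 were higher and 5 lower, with a median of +0.12 (camera adjusted p = 2.8e-09). With an estimated correlation, which was 0.0063 for this list, the camera adjusted p was 0.061. That correlation is below the preset 0.01, so the weaker call does not come from a higher correlation between these genes. The settings also differ in degrees of freedom, which are far fewer with an estimated correlation. In fry, which tests for a shared direction without comparing the list with other genes, the adjusted p was 0.026. The mean score of the list lay above every WT-labelled head in each KO-labelled head (0.06 ± 0.02 against −0.06 ± 0.03, SD, n = 3 each; exact permutation test, two-sided p = 0.1). Adjusted over the list alone, 8 members rose, and over all genes tested 0 passed. The cyclin gene Ccng1 was 1.42 times as high (11.55 ± 0.26 against 11.04 ± 0.01, SD, n = 3 each; limma adjusted p over the list alone, 0.0075) and Phlda3, an inhibitor of AKT signalling, 1.27 times (0.0075). The stress-response gene Sesn2 was 1.21 times as high and Trp53inp1, a regulator of cell death and autophagy, 1.16 times, both with a limma adjusted p of 0.017 over the list alone. The remaining members of the 8 were Zmat3 (+0.32), the nuclease gene Aen (+0.21), the DNA polymerase gene Polk (+0.21) and Apaf1 (+0.15), which encodes the scaffold of the apoptosome. Mdm2 differed by +0.09 and Plk3 by −0.24, and neither passed. The median stayed between 0.10 and 0.13, and the list past the threshold, with each head left out in turn. Of the list's tested members, 0 lie on chromosome 2. A second list of p53 targets, drawn up after this result was seen, with 22 tested and 0 shared genes, had a median of +0.017 (unadjusted camera p 0.10).

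**Figure D2:**
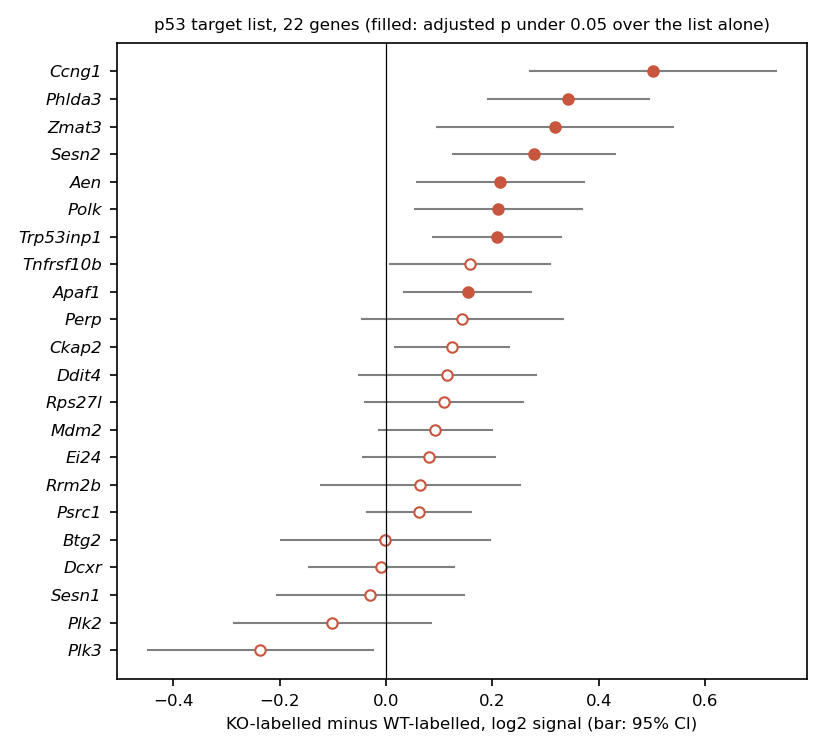
Difference in log2 signal between KO-labelled and WT-labelled heads (x axis) for the 22 tested p53 target genes (y axis), n = 3 heads per group; points are the limma estimates, bars their 95% confidence intervals, and filled points passed an adjusted p of 0.05 over the list alone. The 8 filled points lie between +0.15 and +0.50, and 5 genes lie below 0.

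Genes of neuronal differentiation fell as a list with the preset correlation, 29 of 32 being lower (median −0.12, camera adjusted p = 1.6e-04). The call was lost with an estimated correlation (adjusted p = 0.77), as these genes varied together between heads (estimated correlation 0.66), and the list's score gave an exact permutation p of 0.3. It was also lost without WT 2 (median −0.071), without KO 3 (−0.056) and with Xist signal as a covariate (−0.072). Since Xist is high in WT 2 alone, the covariate is not a check separate from leaving out WT 2. The proneural gene Neurod1, on chromosome 2, differed by −0.46 and the neurofilament gene Nefm by −0.28, and 0 members passed when adjusted over the list alone. Neural progenitor genes (21 tested, median −0.03, adjusted p = 0.16) were not called. Among them Sox9 (−0.19), Vim (−0.10, on chromosome 2), Hey1 (−0.20) and Prom1 (−0.12) had the smallest p-values.

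Patterning genes of the forebrain and midbrain (38 tested, 26 lower, median −0.04) were not called as a list (camera adjusted p = 0.11). Lhx2, a forebrain selector gene on chromosome 2, fell when adjusted over the list alone (10.96 ± 0.12 against 11.29 ± 0.08, SD, n = 3 each; 0.80 times, limma adjusted p over the list alone 0.019). The cortical regulators Emx2 (−0.32) and Emx1 (−0.27) and the homeobox gene Dlx5 (−0.30) did not pass. Genes of the eye and lens (12 tested, 10 lower, median −0.10) fell as a list with the preset correlation (adjusted p = 0.028) but not with an estimated one (adjusted p = 0.54). The call was also lost without WT 1 (adjusted p = 0.097), WT 3 (0.059) or KO 1 (0.22). Its members with the smallest p were Pmel (−0.50), which passed when adjusted over the list alone, and the retinoic acid synthesis gene Aldh1a1 (−0.89), which did not.

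**Figure D3:**
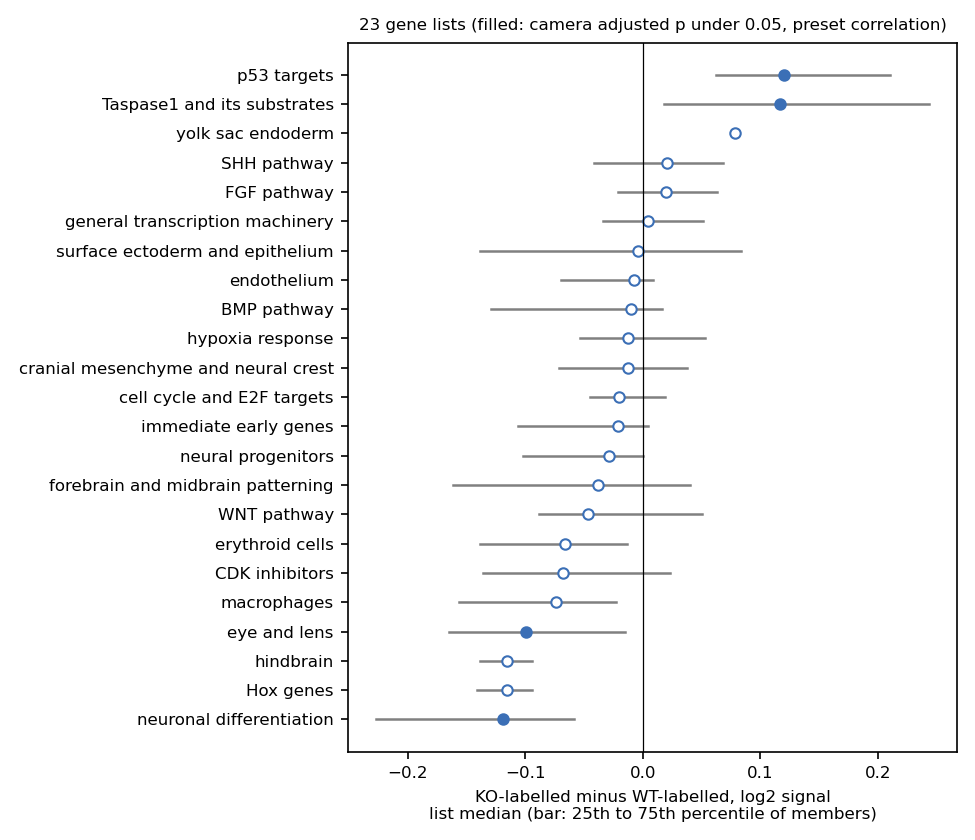
Median difference in log2 signal between KO-labelled and WT-labelled heads (x axis) for the 23 tested gene lists (y axis), n = 3 heads per group; bars span the 25th to 75th percentile of the list's genes and filled points passed a camera adjusted p of 0.05 with the preset correlation. The p53 target list has the highest median, at +0.12, and the neuronal differentiation list the lowest, at −0.12; 4 lists are filled.

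Of the signalling lists, 0 were called by camera. In fry's test for change in either direction, WNT passed (adjusted p = 0.018). In the WNT pathway (17 tested, median −0.05, camera adjusted p = 0.32) 3 members fell when adjusted over the list alone: the secreted WNT enhancers Rspo3 (0.80 times) and Rspo1 (0.80 times) and the secreted antagonist Sfrp1 (0.88 times), each with a limma adjusted p of 0.0067 over the list. The BMP pathway (16 tested) had a median of −0.01, with Id4 at −0.34, Bmp6 at −0.27 and Msx2 at −0.20. The SHH pathway (13 tested) had a median of +0.02, with Gas1 at −0.16, Boc at −0.21 and Foxf1 at +0.26. The FGF pathway (17 tested) had a median of +0.02. None of the members named for these pathways passed outside WNT. The hypoxia response (median −0.01, Pgk1 at −0.11), immediate early genes (−0.02) and the few bright Hox genes (3 tested, −0.12) were not called either. In the general transcription machinery (19 tested, median 0.0047, camera adjusted p = 0.50), Polr2a rose and Taf6 fell when adjusted over the list alone (1.17 and 0.89 times, limma adjusted p 0.0062 and 0.028), and Taf5 differed by +0.16.

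Lists of markers of other cell types were not called by camera. Camera adjusted p-values were 0.79 for cranial mesenchyme and neural crest, 0.43 for endothelium, 0.11 for erythroid cells, 0.16 for macrophages, 0.79 for surface ectoderm, 0.26 for hindbrain and 0.43 for yolk sac endoderm, with medians of −0.01, −0.01, −0.07, −0.07, −0.0039, −0.12 and +0.08. Hindbrain rested on 3 genes and yolk sac endoderm on 2. Single members fell when adjusted over their list alone: the endothelial gene Ramp2 (−0.32, limma adjusted p 0.0099), the embryonic globin Hbb-bh1 (−0.21, 0.030), the complement gene C1qb (−0.30, 0.029) and the tight-junction gene Cldn6 (−0.32, 0.037). Sox10 (−0.38), Dcn (+0.36), Tfap2c (−0.30, on chromosome 2), Cdh1 (+0.16) and Spint2 (−0.16) did not pass.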

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

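The tests of this part were chosen after the patterns were seen, except the one on neighbouring repeated genes, to which the part on the family's clusters was added afterwards. Probe sets that carry several gene symbols were outside the gene comparison. Among all 19615 probe sets above the brightness filter, 9 passed adjusted p 0.05 in limma, and all 9 belong to 1 repeated gene family, annotated to Gm21158, Gm3893, Gm7819, Gm10590, Gm5859, 4933409K07Rik and, for some, 4930578G10Rik, so no single gene can be named. They are not separate measurements, since they are annotated to the same genes and a pair of them held the same values. Their mean log2 signal was 7.58 ± 0.05 in KO-labelled and 9.63 ± 0.30 in WT-labelled heads (SD, n = 3 each), a difference of −2.05, lower in 3 of 3 KO-labelled heads. As a ratio of signals this is 4.16-fold; how much of the lower signal is background is not known here, so it is no ratio of transcripts. The adjusted p of the 9 in limma was at most 0.0084. With quantile normalization the mean difference was −2.08 and with median centring −2.05.

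A candidate explanation for the repeated family is a difference in its copies or their sequence between the embryos. Of its 7 members located in assembly GRCm38.p6, 0 lie on chromosome 2 (they lie on chromosome 4), so linkage of these copies to Tasp1 does not account for it. Copies not placed in that assembly, and an effect of chromosome 2 DNA on genes elsewhere, were not tested. A loss of the whole repeated block, with every copy of the neighbouring genes, is argued against by the 3 probe sets for Ccl27 copies. These read 9.33 to 10.02 in WT-labelled heads and differed by −0.13 to −0.11 (median SE 0.085). Over 12 probe sets of the neighbouring genes, some holding the same values, the median difference was −0.11. The probe sets other than Ccl27 had WT-labelled means of at most 7.45. This is below the family's 7.58 in KO-labelled heads, so they had little room to show a loss. Those for Ccl19 differed by −0.02 to 0.04, and those for Ccl21 copies, which held the same values, by −0.39 (SE 0.11), lower in 3 of 3 KO-labelled heads, without passing (limma adjusted p = 0.79). Since all 12 are annotated to at least 1 gene outside the family's clusters, a loss limited to those clusters stays open, as do a loss of the family's copies only and a change in their transcription in KO-labelled heads; of the 10 splits of the 6 heads into 3 and 3, 1 gave a mean difference as large, the real one (2.05 against 0.87 for the next), and 10 splits are too few for a share under 0.05.

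Genes of chromosome 2, which carries Tasp1, were over-represented among those with an unadjusted p under 0.01 (41 of 939, 4.37%; the next chromosome 2.28%; odds ratio against all others 2.99, two-sided Fisher's exact p = 2.5e-08, or 5.0e-07 after Bonferroni correction over 20 chromosomes), although genes on 1 chromosome are not independent. A candidate explanation is DNA of another strain carried along with the targeted allele, and the nearer 471 genes to Tasp1 in gene order held 32 (6.79%) against 9 of the farther 468 (one-sided Fisher's exact p = 1.7e-04). The excess did not centre on Tasp1, however: the nearest 235 genes held 7 (2.98%; one-sided Fisher's exact p = 0.070 against the other chromosomes) and the next 235 held 25 (10.6%), so carried DNA stays open, with neither the extent of such DNA nor where strains differ given in the sources used here. Probes mismatched only to transcripts of the carried DNA would lower signals in KO-labelled heads. As the explanation of all 41 genes such mismatches are argued against, since 61.0% were lower (95% Clopper-Pearson interval 44.5 to 75.8), against 66.9% elsewhere. Mismatches in the WT-labelled heads' own transcripts would act the other way, so mismatches in both groups stay open. An effect of Taspase1 loss on these genes stays open and untested, and of the 10 splits 1 gave as high a share, the real one (4.37% against 2.56% for the next), too few splits for a share under 0.05.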

How the results depend on the processing

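Array quality weights and the omission of chromosome 2 genes were chosen after seeing the data; the other alternatives were fixed before. The count of 0 genes in limma became 1 with quantile normalization, median centring or a 60% filter (Caprin2 each time), 2 without the filter (Caprin2 and Mir9-1), 3 at adjusted p under 0.10, 5 with array weights and 9 over all probe sets (the repeated family). It was 0 with either pseudocount, averaged probe sets, Xist signal, no trend, robust fitting, an ordinary test, a 1.5-fold minimum and chromosome 2 or the sex chromosomes left out, and 0 to 6 with a head left out. The cause was not tested. With the replicate block there were 0 genes and 4 lists. Same-numbered heads had residual correlations of −0.17, −0.11 and −0.21, so they did not deviate together. Among differently numbered heads, WT 1 with KO 3 (0.27), WT 2 with KO 1 (0.21) and WT 3 with KO 2 (0.28) were positive and the rest negative. Residuals within a group sum to 0 for each gene, so correlations of both signs are forced. The signs therefore do not show which heads were matched, if any. Whether heads were matched across the numbers is not given in the labels.

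The Tasp1 difference ran from 0.12 to 0.31 and that of Cdkn2a from 0.03 to 0.09 with a head left out, and neither passed under any alternative. Both genes fall below the 60% filter and have no value there, and neither has the eye and lens list, of which 1 gene is left. The count of 4 lists became 0 with an estimated correlation, where medians are as before by construction (+0.12 for p53 targets and for Taspase1 and its substrates, −0.12 for neuronal differentiation, −0.10 for eye and lens), 1 with fry for a shared direction (p53 targets), 3 with the 60% filter or without chromosome 2 genes, 5 without the filter (Hox genes added), and 3 to 6 with a head left out. In fry's test for change in either direction, 5 lists passed: surface ectoderm (adjusted p = 0.014), p53 targets (0.014), transcription machinery (0.018), WNT (0.018) and Taspase1 and its substrates (0.038). The p53 list kept its call in all alternatives but the estimated correlation, with adjusted p from 2.3e-11 to 0.061 over those that keep all heads, and medians of 0.10 to 0.13 with a head left out. Taspase1 and its substrates lost its call with the 60% filter (0.067), array weights (0.061) and without chromosome 2 genes (0.067), the first and last because Tasp1 is left out, and its median ran from −0.014 to 0.19 with a head left out. Neuronal differentiation lost its call with Xist signal (−0.072) and ran from −0.23 to −0.056 with a head left out, eye and lens from −0.13 to −0.084; the cause was not tested. Forebrain and midbrain patterning, otherwise not called, was called with the 60% filter, with Xist signal and without WT 2 or KO 3. Xist being high in WT 2 alone, the covariate and the omission of that head are not separate checks.

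Kmt2a and Kmt2b, never called, changed sign: Kmt2a ran from −0.014 to 0.19 and Kmt2b from −0.014 to 0.069 with a head left out, and Kmt2b was −0.0043 with Xist signal and −0.0019 with array weights. Other named genes kept their sign but moved with a head left out. Aldh1a1 ran from −1.17 to −0.50 and Foxf1 from 0.12 to 0.38. Boc ran from −0.30 to −0.13, Nefm from −0.38 to −0.15, Id4 from −0.40 to −0.21 and Msx2 from −0.26 to −0.13. For Hey1 the range was −0.28 to −0.13 and for Prom1 −0.15 to −0.079. Signal over background limits dim genes such as Cdkn2a.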

Other observations

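The telencephalic and midbrain lists, the gene families and the counts over splits described here were chosen after the data were seen, except the splits for p53 targets and for lists, the second p53 list and the omission of single WT heads, which were set before their results. All 11 tested genes of a telencephalic list, drawn up after 5 of its members had been seen lower, were lower in KO-labelled heads, with a median of −0.17. In the patterning list fixed before, Lhx2 passed in limma when adjusted over the list alone, while Emx1 and Emx2 (adjusted p = 0.059 each), Dlx5 and Dlx2 (0.12 each) did not; Lhx2 and Dlx2 lie on chromosome 2, as Tasp1 does. No p of the telencephalic list is independent evidence of its direction; with an estimated correlation camera gave an adjusted p of 0.12 over 3 lists chosen later. The median was −0.19 with quantile normalization and −0.16 with median centring. A list of 12 genes of the midbrain and isthmus had a median of +0.044 (exact permutation test of its score, two-sided p = 0.6).

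A smaller share of forebrain in the dissected KO-labelled heads may lower neuronal and telencephalic genes and raise midbrain genes. The midbrain median of +0.044 was smaller than the spread of that list's score within groups (SD 0.08), so this cannot be told apart from a change within the forebrain. A single WT head with more neurons was tested by leaving out each WT head. The neuronal median nearest to 0 was then −0.071, without WT 2, against −0.12 over all heads, so that head contributes but was not shown to account for the whole difference. Leaving out KO 3, which was not part of that test, brought the median nearer to 0, to −0.056. The list's mean scores overlapped between the groups. They were 0.09, 0.18 and −0.06 in WT 1, WT 2 and WT 3, and 0.12, −0.11 and −0.22 in KO 1, KO 2 and KO 3.

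The rise of p53 targets was weighed against array and chance explanations. Without WT 1, the array that stands apart, the median was +0.13, and without WT 2, the only head with high Xist, it was +0.12, so neither head accounts for it. A second list of p53 targets, with 22 tested and 0 shared genes, had a median of +0.017 (unadjusted camera p 0.10), or −0.011 with quantile normalization. A rise of the first list's size was thus not seen in the second list. Whether the second list's genes respond to p53 in this tissue was not tested, so that list does not decide how wide the rise is. Of the 10 splits, 1 gave a median as large in size, the real one (0.12 against 0.06 for the next), and 10 splits are too few for a share under 0.05. A p53 response in part of its targets in KO-labelled heads is a hypothesis consistent with these values, and the protein was not measured.

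For the number of genes in limma the splits carry no information, since all 10 reach a count of 0 by construction (the highest other was 2). For the number of lists, 8 of the 10 splits gave 4 or more, the real one giving 4 and the highest other 5. With an estimated correlation, 0 lists were called in each split. Whatever the count, 10 splits are too few for a share under 0.05. Every split but the real one has KO-labelled heads unevenly on both sides. Such a split still holds part of any difference between the labels, here and for the p53 list, the repeated family and chromosome 2. The split of WT 3, KO 1 and KO 2 from the rest gave 1331 genes at unadjusted p under 0.05, more than the 841 of the real split, which points to structure among the heads other than genotype.

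Some genes separated KO 1 from the other KO-labelled heads, named here after their values were seen. The chemokine gene Cxcl13 read 9.32 in KO 1, 7.72 in KO 2 and 7.77 in KO 3, and 9.45 to 9.72 in WT-labelled heads. The axon guidance receptor gene Robo3 read 7.54, 6.55 and 6.52, and 7.33 to 7.52 in WT-labelled heads. The somatostatin gene Sst, called without WT 1, read 8.78 in WT 1, 9.65 and 9.73 in the other WT-labelled heads, and 8.46 to 8.87 in KO-labelled heads.

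Among 10 gene families chosen by name, the respiratory chain had 63 of 81 genes lower (median −0.04, camera adjusted p = 0.023), which was lost with an estimated correlation (adjusted p = 0.86). Its score was 0.10 in WT 1 and between −0.04 and −0.01 in the other 5 heads.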
